A study of Danio rerio with 20 samples.

How the data were processed

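RNA of zebrafish (Danio rerio) liver tumors and of normal zebrafish livers was measured on 2-colour microarrays, 20 arrays in all. Per the labels, each array carried a liver sample labelled with Cy5 and normal liver RNA labelled with Cy3, so that the second channel served as a common reference on all 20 arrays, and no dye was swapped. Per the labels' protocols, fish were kept at 27 ± 2 °C and 20 µg of total RNA went into each labelling. The group of an array was read from its title, where a C or a T and a number stand for the sample. The 10 C arrays were taken as normal liver and the 10 T arrays as tumor, which matches the 10 and 10 arrays that the series' design text names. Nothing in the labels says how the tumors were sampled or whether each array came from a separate fish, so p-values measure the spread between these samples, which may be partly technical. No scan date or slide batch is given in the sources used here.

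The deposited table holds log2 ratios. The base of the logarithm was read from the values, because within an array the most repeated values lie apart by the log2 of ratios of small whole numbers (1.00, 0.585 and 0.322), as ratios of small whole-number intensities do, after 1 constant per array. Genes were not centred, since probe means over the 20 arrays run from -6.47 to 2.77. The direction of the ratio is not stated. It was taken as likely liver sample over reference from the order of the channels in the labels, and if it ran the other way every sign given here would turn. All pairs of arrays correlate above 0 over the 16512 probes, the lowest at 0.077. Background correction, spot filters and normalization are not given in the sources used here. The table has 0 missing values, so no filter on missing values removed anything. The median log2 ratio lay between -0.141 and 0.205 on the normal arrays and between -0.139 and 0.0341 on the tumor arrays.

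Of 16512 probes, 6088 (36.9%) had 1 gene symbol in the platform annotation, 75 had several and 10349 had none. The Entrez numbers of 6019 probes were found in a RefSeq gene table (assembly GRCz12tu, used for names only), which updated 1 symbol. Probes with the same single symbol were averaged within each array, and each other probe stayed a feature of its own. This gave 15780 features, 5356 of them named, and 504 named features rested on several probes. The 172 spots of actb2 were averaged into 1 feature.

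Signal brightness is not in the table. A share of dim spots was therefore taken from each array as the percentage of its values within 0.00011 of the log2 ratio of 2 whole numbers up to 10, after the constant of the array. It ran from 2.55% to 7.87% on the normal arrays (mean 5.86%) and from 0.594% to 7.16% on the tumor arrays (mean 1.96%). When the constant was shifted to a wrong value, the share was 0.288% to 0.381%. The number of arrays limits the precision.

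Tumor and normal arrays were compared per feature with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over the 15780 features and a threshold of 0.05. The 95% level was used for intervals. Of 45 gene lists fixed before the data were examined, 43 had at least 5 measured members and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 43 lists. The lists of adipocytes and of bile acid and steroid metabolism had too few measured members and were not tested. Camera with an estimated correlation and fry were run beside it. Counts of members were also adjusted over the list alone. Normal liver was set against the reference by testing the mean of the 10 normal arrays against 0 in a fit with both groups. The distance of an array from its own group was the median over features of its absolute difference from the mean of the other arrays of the group, compared with a two-sided permutation test (100000 resamples). Scores of 4 lists were the mean over members of the log2 ratio minus the mean of the normal arrays, and 3 relations between them over the 10 tumor arrays were tested with Pearson's r and Spearman's rho, each with a permutation p (100000 resamples). These steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

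Genes were named by a rule fixed before the data were examined. It takes the 7 largest increases and the 7 largest decreases among called features with 1 symbol, the 3 members with the smallest p of each list, and pcna, cyp1a, fabp10a, vtg1, hbaa1 and prss1, of which vtg1 had no probe of that single name here. A further gene of the rule and 1 of the lists are not reported here. The comparison with the reference names its 7 largest differences each way, a choice made after its values were seen. Further list members and vtg3, esr1 and zp3, named where a paragraph says so, were chosen after their values were seen. One list, of plasma proteins, holds a parvalbumin gene that does not belong there, and it was kept as fixed.

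The fit was tested on simulated data for the comparison of tumor with normal, with 200 of the 15780 features changed. It recovered 78% of 100 changes of 1 log2 unit and 94% of 100 changes of 2 log2 units, with 6 false calls among 178, and it called 3 of 3 lists that had been lifted and 0 others. The simulated noise was drawn independently for each feature. Members of a list did not vary together as they do in the data, so the list result gives no rate of false list calls here.

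The alternatives fixed before the data were examined were 3 scalings between arrays, every probe as its own feature, eBayes with trend and robust, array quality weights, a rank-sum test, a block for the number in the title, a 2-fold minimum and each array left out in turn. Alternatives chosen after seeing the data left out normal replicate 8 and tumor replicate 10, left out tumor replicates 1 and 10, used the dim share as a covariate, left out 324 features that were dim on at least 5 arrays, and ran the lists under 2 more scalings.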

Results

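The series set liver tumors of zebrafish against normal zebrafish liver, with 10 arrays in each group, each hybridised against the same kind of reference, normal liver RNA. Values are log2 ratios to that reference, likely liver sample over reference, and differences are tumor minus normal in log2 units with their SE (n = 10 per group). Over the 16512 probes, with the 172 actb2 spots counted singly, tumor arrays correlated with each other at a mean of 0.592 and normal arrays at 0.404, while a tumor and a normal array correlated at 0.313. Normal replicates 2 and 8 correlated slightly more with the tumor arrays than with the other normal arrays (means 0.453 against 0.438, and 0.188 against 0.186). The share of dim spots differed between the groups, at a mean of 1.96% on tumor arrays and 5.86% on normal arrays.

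The first question was which genes differ between tumor and normal liver. Rankings in this paragraph are among named features that passed the adjusted threshold. The largest difference belonged to si:dkey-7i4.24, which was higher in tumors by 5.96 ± 0.57, or 62.1-fold (adjusted p = 1.78e-06 with limma), and stood between 2.87 and 8.27 on the 10 tumor arrays, all above the normal arrays. The other large increases were stmn1a, whose product binds tubulin (2.36 ± 0.52), the cytoplasmic actin actb1 (2.25 ± 0.33, 4.74-fold), the monocarboxylate transporter slc16a3b (2.24 ± 0.53), the amino acid transporter slc7a3a (2.13 ± 0.52), zgc:175136 (2.11 ± 0.60) and org, a gene known from oocytes (2.04 ± 0.64). Among the largest decreases, the alcohol dehydrogenase adh8a fell by 4.31 (SE 0.59, normal liver 19.9-fold above tumor), and the retinol carrier of plasma, rbp4, fell by 4.03 (SE 0.36, 16.3-fold). The others were the fatty acid desaturase fads2 (-3.73 ± 0.50), the apolipoprotein apoa1a (-3.63 ± 0.44), rbp2a (-3.25 ± 0.40), the glycolytic enzyme gapdh (-3.25 ± 0.38) and the gluconeogenic enzyme fbp1b (-3.14 ± 0.44). For adh8a, rbp4, rbp2a and gapdh, all 10 tumor arrays lay below all normal arrays.

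**Figure D1:**
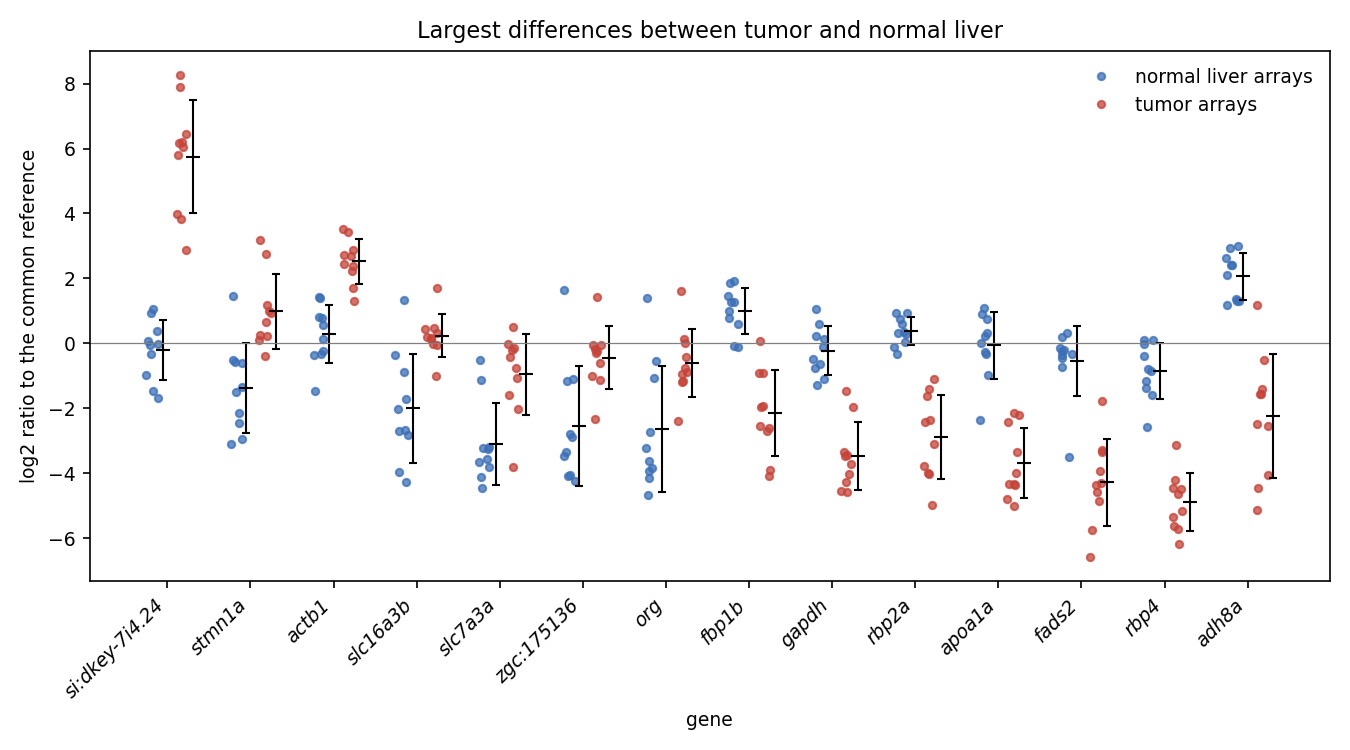
Log2 ratio to the common reference (vertical axis) of the 7 largest increases and 7 largest decreases among named features that passed, one point per array, for 10 normal liver arrays in blue and 10 tumor arrays in red, with black marks for the mean ± SD of each group. The points of si:dkey-7i4.24 do not overlap between the groups, while those of org do.

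In all, 1712 of 15780 features (10.8%) passed the adjusted threshold, 933 of them higher and 779 lower in tumors. Among named features 680 passed, 405 higher and 275 lower. A minimum of 2-fold left 594, with 267 higher and 327 lower, and at 4-fold or more there were 19 increases and 82 decreases. In 83 features the groups did not overlap, where chance gives 0.171 (0.0011% of features). The median difference of all features was -0.0086. With the dim share of each array as a covariate, 55 features passed, 12 of them higher, and the called differences had a median of 0.778 of their size without it. The next counts cover only the 128 genes picked for naming, mostly for a large difference or a small p, not all 680. Of the 128, 93 passed, and 11 of the 93 also passed with this covariate: si:dkey-7i4.24, rhoaa, yars1, rbp4, fads2, apoa1a, rbp2a, gapdh, mat1a, slc37a4a and mylpfa. Of the 93, 81 passed without each array in turn. Without normal replicate 4 or 7, zgc:175136 missed the threshold (adjusted p = 0.0538 and 0.0501), and org did so without any one of 15 arrays (adjusted p up to 0.0803).

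Lists of hepatocyte functions held genes that were lower in tumors. Of 19 measured genes of xenobiotic metabolism 11 fell and 0 rose (14 fell when adjusted over the list alone), among them adh8a, cyp1a (-2.23 ± 0.31, with 9 of 10 tumor arrays below all normal arrays), the monooxygenase fmo5 (-2.14 ± 0.33) and nqo1 (-1.70 ± 0.26). Of 11 plasma protein and iron transport genes 6 fell and 1 rose (6 and 1 over the list alone). Next to rbp4, fetub changed by -2.94 ± 0.38, the copper oxidase ceruloplasmin, cp, by -2.29 ± 0.32, and the liver fatty acid binding protein fabp10a by -3.11 ± 0.66. Of 11 lipoprotein and lipid transport genes 6 fell and 0 rose (7 over the list alone), among them apoa1a, scp2a (-2.19 ± 0.32) and apoba (-1.49 ± 0.28), whose 2 probes disagreed at -3.30 and 0.33. Camera gave adjusted p = 3.9e-09, 8.26e-06 and 3.42e-05 for these 3 lists, and adjusted p = 0.082, 0.11 and 0.11 with an estimated correlation.

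Of 24 genes of amino acid and urea metabolism 9 fell and 2 rose (13 and 2 over the list alone). The methionine adenosyltransferase mat1a changed by -2.49 ± 0.29, the tyrosine-degrading hgd by -2.68 ± 0.37 and dmgdh by -1.35 ± 0.28. Glutamine synthetase, glulb, a member named after its value was seen, was higher by 1.36. In fatty acid oxidation 4 of 11 fell and 1 rose (4 and 1 over the list alone), with the peroxisomal enzymes cat at -2.97 ± 0.39 and hsd17b4 at -1.20 ± 0.23 and the hydratase echs1 at -0.86 ± 0.19. The member that rose was hmgcs1, which is an enzyme of cholesterol synthesis. In gluconeogenesis and glycogen 2 of 5 fell, fbp1b and slc37a4a (-1.22 ± 0.28), and 1 rose, pfkfb3 (0.79 ± 0.22), whose product favours glycolysis; over the list alone 4 fell and 1 rose. Of 21 hepatocyte transcription factors 4 fell and 1 rose (6 and 2 over the list alone), with foxa2 at -1.08 ± 0.27, pparab at -0.91 ± 0.21 and prox1a at -0.64 ± 0.15. The 4 lists had camera adjusted p = 1.51e-05, 0.0216, 0.0218 and 0.0304, and adjusted p = 0.234, 0.39, 0.299 and 0.39 with an estimated correlation. Without tumor replicates 1 and 10, which stood apart from the other tumors, the last 3 of these lists missed the threshold (adjusted p = 0.15, 0.0739 and 0.221), as they did without normal replicate 8 and tumor replicate 10 (adjusted p = 0.0577, 0.0557 and 0.0662), and the transcription factor list also did so with the dim share as a covariate (adjusted p = 0.175).

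Lists of the cytoskeleton, epithelia and matrix held genes that were higher in tumors. Of 34 genes of the actin cytoskeleton and adhesion 16 rose and 0 fell (19 over the list alone), led by the small GTPases rhoaa (1.39 ± 0.17) and rac1a (1.05 ± 0.15) and by actb1. The mean of the 172 actb2 spots rose by 0.90, a value chosen after it was seen, and 162 of those spots passed one by one. These spots measure 1 gene on the same arrays, so they are not separate evidence. The groups overlapped, with array means of 0.41 to 2.56 on normal and 1.44 to 3.56 on tumor arrays. Of 23 epithelial and bile duct genes 4 rose and 0 fell (4 over the list alone), with epcam, a surface protein of epithelia, at 1.32 ± 0.33, notch3 at 0.63 ± 0.18 and lgals3a at 0.48 ± 0.14. Without any one of 6 arrays notch3 missed the threshold (adjusted p up to 0.0562), and lgals3a did so without any one of 9 (adjusted p up to 0.0661). Of 28 genes of extracellular matrix and fibroblast or stellate cells 7 rose and 1 fell (7 and 1 over the list alone), with the protease inhibitor timp2a 2.14-fold higher, postna at 0.63 ± 0.16 and the metalloprotease mmp14a at 0.71 ± 0.19, whose 2 probes gave 1.07 and 0.34. Camera gave adjusted p = 1.16e-12, 0.00617 and 0.0304, and with an estimated correlation adjusted p = 0.082, 0.234 and 0.479. The matrix list missed the threshold without tumor replicates 1 and 10 (adjusted p = 0.326) and without normal replicate 8 and tumor replicate 10 (adjusted p = 0.258).

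The next 5 lists concern RNA and protein production, folding and breakdown. In mRNA splicing 10 of 26 rose (16 over the list alone), among them sf3b4 (1.27 ± 0.23), hnrnpaba (0.87 ± 0.18) and khdrbs1a (0.90 ± 0.21). In the nucleolus list 8 of 19 rose (10 over the list alone), with nolc1 at 0.89 ± 0.18, gnl3 at 0.83 ± 0.18 and npm1a at 0.97 ± 0.21, whose 2 probes gave 0.72 and 1.22. Of 6 aminoacyl-tRNA synthetase genes 4 rose (4, with 1 lower, over the list alone), with yars1 at 1.34 ± 0.16 and lars1b at 0.82 ± 0.16. In the list of chaperones and the unfolded protein response 9 of 28 rose (14 over the list alone), with the endoplasmic reticulum chaperones canx at 1.06 ± 0.18 and dnajb11 at 1.54 ± 0.28 and the cochaperone stip1 at 0.66 ± 0.12. Of 15 proteasome genes 3 rose (5 over the list alone), with psme3 at 0.60 ± 0.15 and psmd11b at 0.35 ± 0.11, which missed the threshold without any one of 13 arrays (adjusted p up to 0.0761). No member of these 5 lists fell over all features. Their camera adjusted p was 3.12e-08, 1.72e-06, 0.00133, 9.98e-08 and 0.0109, and with an estimated correlation adjusted p = 0.234, 0.157, 0.222, 0.082 and 0.462. The proteasome list missed the threshold without tumor replicates 1 and 10 (adjusted p = 0.416) and without normal replicate 8 and tumor replicate 10 (adjusted p = 0.104), and the nucleolus list with the dim share as a covariate (adjusted p = 0.169). Of 16 ribosomal protein genes limma called 0, as did adjustment over the list alone, 0 had an unadjusted p under 0.05 and the rank-sum test called 0; the camera adjusted p was 0.956.

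Of 9 genes of cholesterol synthesis 6 rose and 0 fell (8 over the list alone), with acat2 2.83-fold higher, fdft1 at 0.68 ± 0.17 and insig1 at 1.17 ± 0.31. The camera adjusted p was 3.66e-06, and adjusted p = 0.111 with an estimated correlation.

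Few genes of cell division passed. Pcna, the sliding clamp of DNA polymerase, rose by 1.17 ± 0.30 (adjusted p = 0.0156), and 2 of 18 DNA replication genes passed, pcna and slbp (2 over the list alone). Slbp missed the threshold without any one of 14 arrays (adjusted p up to 0.0749). Among 24 genes of mitosis and the cell cycle 3 rose (5 over the list alone), stmn1a, the cyclin ccnd1 (2.39-fold, its 2 probes at 0.96 and 1.55, the first not past the threshold) and anln (1.21 ± 0.38), which missed the threshold without any one of 13 arrays (adjusted p up to 0.0846). In the list of histones and chromatin 3 of 22 rose (6 over the list alone), with the deacetylase hdac1 at 1.08 ± 0.22 and the methyltransferase ezh2 at 1.41 ± 0.33, and anp32a, which missed the threshold without any one of 9 arrays (adjusted p up to 0.0592). The lists of DNA replication, mitosis and histones had camera adjusted p = 0.0155, 0.0139 and 0.00033, and adjusted p = 0.521, 0.494 and 0.39 with an estimated correlation. Tumor replicates 10 and 1 had the highest DNA replication scores of the tumors, replicate 10 at 1.75, while the other 8 lay between 0.01 and 0.28, inside the range of the normal arrays (-0.48 to 0.55). The highest normal score was that of normal replicate 8, and the ovary scores were highest on that array and tumor replicate 10 (2.83 and 2.57); the ovary and mitosis lists share ccnb1 and fbxo5. Without tumor replicates 1 and 10 the lists of DNA replication and of mitosis missed the threshold (adjusted p = 0.334 and 0.326). Mitosis also did so with the dim share as a covariate (adjusted p = 0.246) and after centring and scaling (adjusted p = 0.0532).

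**Figure D2:**
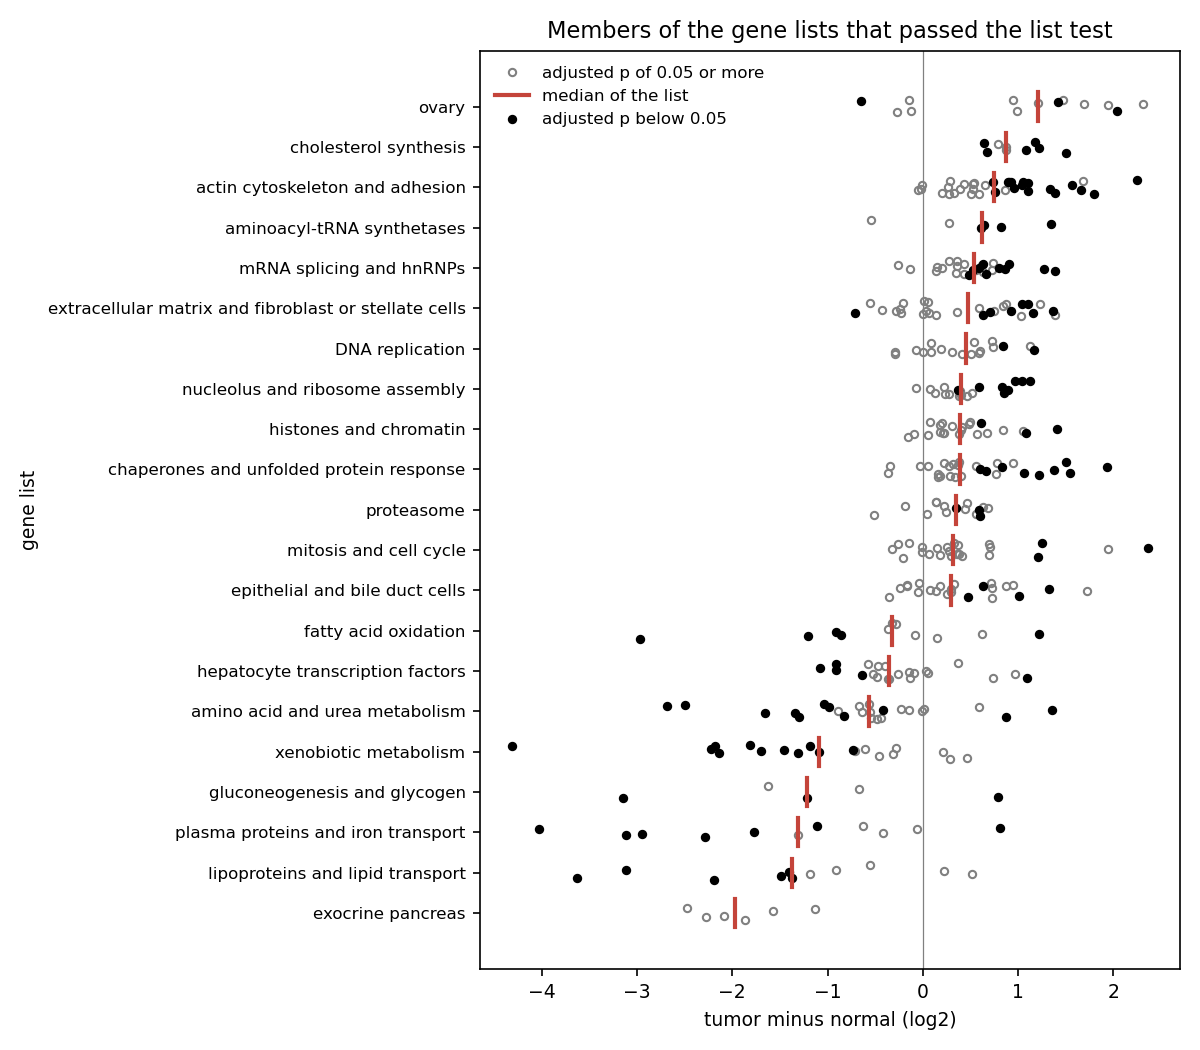
Difference of each member (tumor minus normal, log2, horizontal axis) in the 21 gene lists that passed the list test, by list. Filled points are members with an adjusted p below 0.05 over all features, open points the others and red bars the list medians, and all 6 exocrine pancreas genes lie below 0 as open points.

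Lists of markers of other tissues were tested as well. The 6 exocrine pancreas genes had a median of -1.98, with 0 called by limma over all features and 0 by the rank-sum test, 4 with an unadjusted p under 0.05 and 4 lower over the list alone, and cel.2 at -2.28 ± 0.75, cpb1 at -2.09 ± 0.70 and prss1 at -2.48 ± 0.88 (adjusted p = 0.0526, 0.0581 and 0.0741). The list passed camera (adjusted p = 0.00617), and had adjusted p = 0.404 with an estimated correlation, which was 0.945. Of 13 ovary genes 2 rose and 1 fell (6 and 1 over the list alone). Org and the zona pellucida gene zpcx (1.42 ± 0.46) were higher and the germ cell gene nanos3 lower (-0.65 ± 0.16), and zpcx missed the threshold without any one of 15 arrays (adjusted p up to 0.0813). The ovary list had a camera adjusted p of 0.0459, adjusted p = 0.578 with an estimated correlation, and missed the threshold when arrays were centred (adjusted p = 0.0696; 0.0014 to 0.873 over the alternatives). The oocyte gene zp3, which did not pass, stood at 2.56 on normal replicate 8 and 2.39 on tumor replicate 10, against a median of -1.03 over the tumor arrays. In the erythrocyte list 1 of 15 genes fell, hbae3 (-0.44 ± 0.14; 0 over the list alone; lost without any one of 13 arrays, adjusted p up to 0.0737), with hbaa1 at -1.16 ± 0.53 (adjusted p = 0.162) and a camera adjusted p of 0.164. Of 19 leukocyte genes limma called 0 (1 at an unadjusted p under 0.05, 0 by the rank-sum test, 0 over the list alone), of 6 endocrine pancreas genes 0 (0 at an unadjusted p under 0.05, by the rank-sum test and over the list alone), and of 10 intestine genes 1, rbp2a (1 over the list alone), with camera adjusted p = 0.22, 0.393 and 0.717. With the dim share as a covariate the leukocyte list passed (adjusted p = 0.000461).

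**Figure D3:**
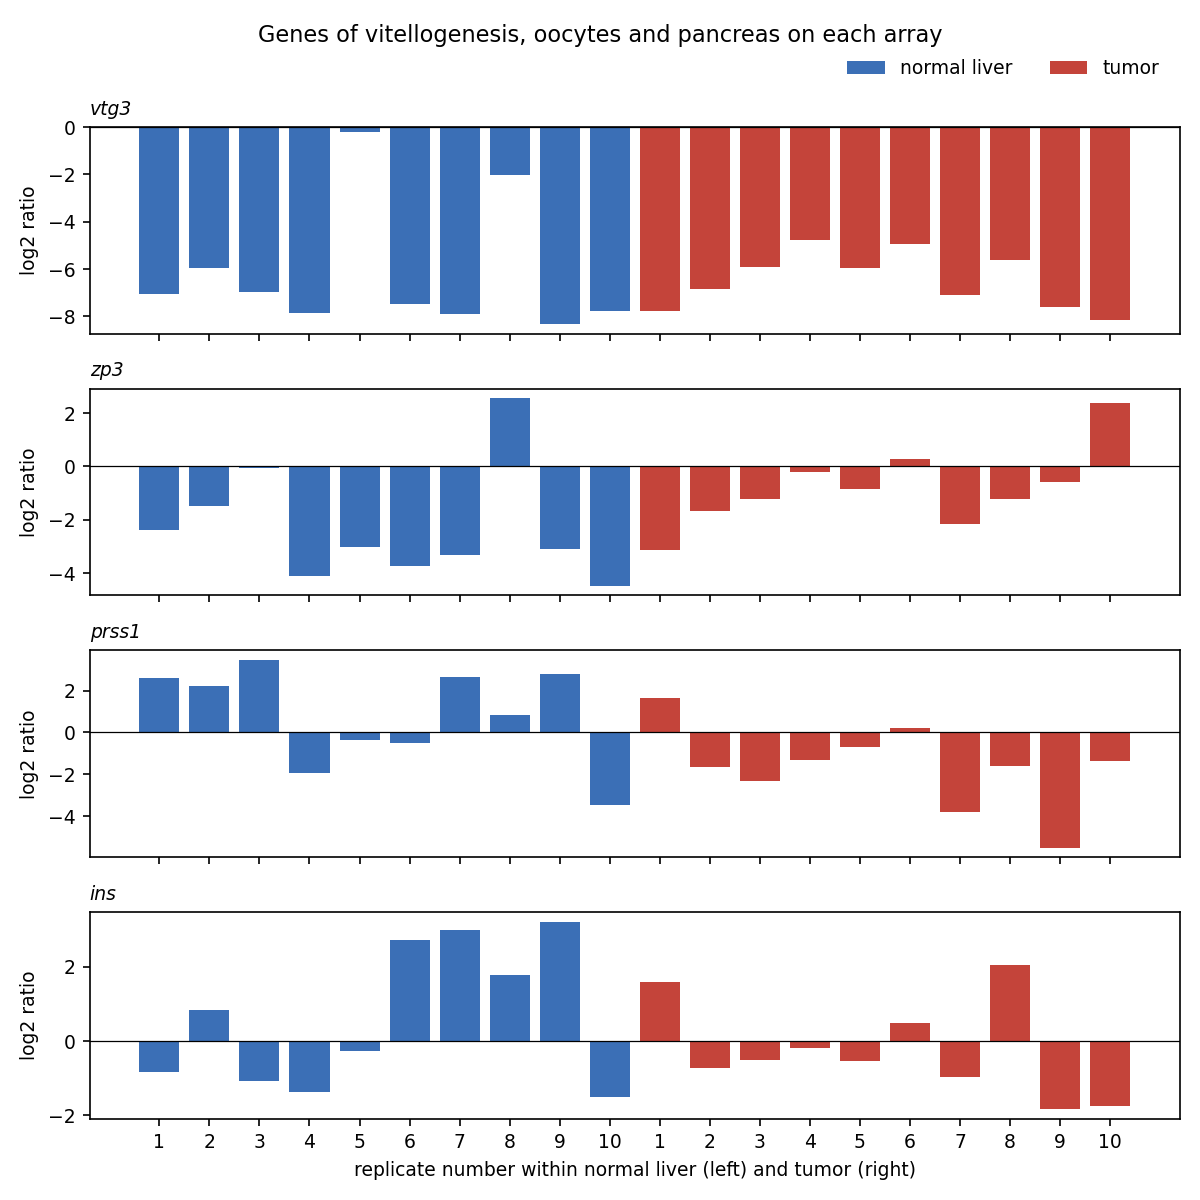
Log2 ratio to the reference (vertical axes) of vtg3, zp3, prss1 and ins on each of the 10 normal liver arrays (blue) and 10 tumor arrays (red), by replicate number. Bars start at 0; vtg3 is near 0 on normal replicate 5 alone, at -0.20, and zp3 is highest on normal replicate 8 and tumor replicate 10.

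Normal liver was also set against the reference. Of 15780 features 3943 differed, 1794 higher and 2149 lower in the 10 normal livers, and 706 of them by at least 2-fold, 196 higher and 510 lower. Liver was always labelled with Cy5 and the reference with Cy3, so dye effects that depend on the gene cannot be told apart from these differences. The p-values of limma here rest on the spread between arrays within the groups. Other normal liver RNA was not measured as a reference, so the differences hold for the reference used here. The yolk precursor gene vtg3 was the lowest, at -6.15 ± 0.62 (SE, adjusted p = 1.45e-06 with limma, reference 70.9-fold higher). It stood at -0.20 on normal replicate 5, at -2.02 on normal replicate 8 and between -8.31 and -4.77 on the other 18 arrays, tumors included, and its difference between tumor and normal liver did not pass (-0.32 ± 0.87, adjusted p = 0.848; -3.41 to 0.86 over the alternatives, with the lowest value and the lowest adjusted p, 0.0954, under the dim share as a covariate). Probes named slc22a23 (-6.13 ± 0.65), chst6 (-5.66 ± 0.63), pax9 (-5.53 ± 0.50), tmem266 (-3.88 ± 0.45), hif1al (-3.09 ± 0.32) and slc7a3a (-3.09 ± 0.37) followed among the named features. The oestrogen receptor gene esr1 was also below the reference, at -2.01 ± 0.32. Highest of the named features in the normal livers were grna.1 (2.31 ± 0.45), si:ch73-359m17.9 (2.22 ± 0.46), tcnba (2.18 ± 0.49), adh8a (2.07 ± 0.42), the growth factor igf2a (1.99 ± 0.25), the invariant chain cd74a (1.90 ± 0.30) and cldn3c (1.84 ± 0.37).

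The distance of arrays from their own group was compared next. The median absolute difference from the own group was 0.272 ± 0.121 on tumor arrays and 0.310 ± 0.0846 on normal arrays (SD, n = 10 each; difference -0.0383, two-sided permutation p = 0.424). Taken as 1 minus the correlation with the mean of the other arrays, the distance was smaller among tumors, 0.301 ± 0.0775 against 0.428 ± 0.130 (permutation p = 0.00844). All values are ratios to normal liver RNA, so a shared difference of the tumors from normal liver by itself raises their correlation. That measure therefore cannot show that tumors are more alike than normal livers.

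Over the 10 tumor arrays, the DNA replication score was compared with 3 other list scores. It had r = -0.48 with plasma proteins and iron transport (permutation p = 0.212, adjusted p = 0.212; rho = -0.12, p = 0.759) and r = -0.46 with ribosomal proteins (permutation p = 0.187, adjusted p = 0.212; rho = -0.31, p = 0.386). With extracellular matrix and fibroblast or stellate cells it had r = 0.82 (permutation p = 0.00984, adjusted p = 0.0295), while rho was 0.27 (p = 0.447, adjusted p = 0.671). Without tumor replicates 1 and 10, the 2 arrays farthest from the median score, r was 0.28, -0.18 and -0.41, so that the relation with extracellular matrix rests on those 2 arrays.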

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

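The tests of other splits, brightness, ratios drawn toward 0 and carried pancreatic RNA were chosen or set down only after the results they bear on had been seen. Among 266 groups of 10 arrays, 21 had an array far from the nearest other one relative to the range of the group (Dixon's test at the 95% level), where chance gives about 1 in 20 (13.3). On tumor replicate 9 these were stip1 at -0.162, dnajb11 at -1.318, clec14a at 0.840, cpb1 at -5.53, stat2 at -1.959 and fetub at 0.559, while fetub was between -3.55 and -1.48 on the other tumors. Normal replicate 8 stood out for zgc:175136 at 1.631, slbp at 1.19 and anln at 1.355. Tumor replicate 10 stood out for mbl2 at 3.364 and pole3 at 1.613, and tumor replicate 1 for hnrnpaba at 2.34 and eif4g1a at 1.459. The others were fads2 on normal replicate 6 (-3.494), ccn2a on normal replicate 10 (4.023), canx on normal replicate 9 (0.006), stip1 on normal replicate 4 (-1.01), pdx1 on tumor replicate 7 (0.862), postna on normal replicate 1 (-1.202), prox1a on normal replicate 3 (-0.325) and myhz1.3 on normal replicate 2 (1.305).

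Chance was set against the calls by splitting the 20 arrays in other ways. The real split gave 1712 features, 1 of 100 splits gave as many, the real one, and the highest of the others called 0. A chance split thus rarely gives so many calls, though 1 of 100 is the smallest share these splits can show. That reading needs arrays that are independent samples, which the labels do not state. For the lists the real split gave 21, and 4 of 100 splits gave as many, with 22 as the highest other and 10 as the median of the others. That share, the real split included, lies too near 0.05 to exclude chance for the number of lists, and another split called more. A median of 10 lists in random splits shows that members of a list vary together across arrays more than the preset correlation allows.

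Tumor arrays were brighter than normal arrays by the share of dim spots, so each array was placed, on the features called when it was left out, between the normal mean (0) and the tumor mean (1). Brighter normal arrays lay nearer to the tumors (r = -0.69, permutation p = 0.0278; rho = -0.42, p = 0.232; r = -0.48 without the 2 arrays farthest from the median, n = 10, so the relation rests partly on those), and tumor replicate 9, with a dim share of 7.16%, lay at 0.265, inside the range of the normal arrays (-0.144 to 0.404). The trend of the normal arrays, read at the mean dim share of the tumors, gave a position of 0.362 (95% interval 0.128 to 0.597), below the mean of the tumors, 0.890 ± 0.285 (SD), though that share lies outside the range of the normal arrays, and with 1 slope within both groups over all 20 arrays a gap of 0.488 (95% interval 0.224 to 0.751) remained at the same share, of 0.778 without it. These values cannot decide whether brightness is the whole cause. The trend may not be straight, and the dim share is only a stand-in for brightness. Error in the share would flatten the trend and leave a gap by itself. On tumor replicates 4 and 5 the constant behind the share rests on only 19 and 22 values. At least a part of each difference may come from brightness: with the dim share as a covariate the called differences shrank to a median of 0.778 of their size (quartiles 0.581 and 0.937), their standard errors grew to a median of 1.43 times, and 55 features were called. The tumor state itself, the difference the design names, stays open beside it.

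Many increases ran toward the level of the reference. Of 933 features called higher, 461 (49.4%) moved closer to 0, slc7a3a and org among them. No such share was taken for features called lower or not called. These moves may come from ratios drawn toward 0 on the tumor arrays. A ratio drawn toward 0 does not pass it, and 567 of the 933 had a tumor mean above 0 by more than 2 SE, which argues against this as the whole cause for those. Some of the 567 are also among the 461, so a part of their increase may still come from it. For features outside the 567 it stays open. Features at least 2-fold below the reference in the odd-numbered normal arrays lay higher on tumor arrays than on the even-numbered ones, by 0.319 on average. The 95% interval, 0.019 to 0.620, holds only the spread of the tumor arrays. The even-numbered normal arrays themselves ran from -0.38 to 0.52, so an upward shift of the group is not settled. Features at least 2-fold above the reference shifted by -0.036 ± 0.368 (SD, n = 10), so that an average downward shift cannot be told apart from none. The tumor arrays differed in this. Replicates 2 to 8 shifted toward 0 in both sets (0.34 to 0.78 and -0.49 to -0.06). Replicates 1, 9 and 10 shifted away from 0 in both (-0.38 to -0.08 and 0.26 to 0.58).

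The exocrine pancreas list was lower in tumors, with a mean score of -1.90 ± 1.64 on tumor arrays and 0 ± 2.00 on normal arrays (SD, n = 10 each, permutation p = 0.033). The pancreas of zebrafish lies along the liver and gut, and different amounts of pancreatic RNA carried with the liver may account for it. The 6 genes, a list fixed before the data were examined, rose and fell together within the groups, with a lowest correlation of 0.919 between 2 of them, as 1 source would give. As a cause of the other decreases it is argued against, since the 779 features called lower kept a median of 1.062 of their difference with the pancreas score as a covariate. Which fish parts were sampled is not known.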

How the results depend on the processing

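The covariate, the left-out dim features, the joint omissions of 2 arrays and the lists under quantile normalization and scaling were chosen after seeing the data. Of the 93 called genes among those picked for naming, none changed direction under any alternative run. Where every probe was its own feature, this followed only the first probe of each gene. The other probe of apoba lay at 0.33 and did not pass. With the dim share as a covariate 82 of the 93 lost their call. Also fixed beforehand were 2 alternatives on missing values, which were void because no value was missing. Dim signal limits low features. The cause of the changes below was not tested, except that a 2-fold minimum removes calls by construction and that the covariate shrank differences and widened their standard errors.

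Called features were 2622 after quantile normalization, 2733 after centring and scaling, 3391 with array quality weights, 594 with the 2-fold minimum and 55 with the dim share as a covariate. Higher ones were 1578 after centring and scaling, 1965 with weights, 267 with the 2-fold minimum and 12 with the covariate. Lower ones were 1225 after quantile normalization, 1426 with weights, 327 with the 2-fold minimum and 43 with the covariate. Leaving out each array in turn gave 1358 to 2148 calls, 715 to 1154 higher and 624 to 994 lower; the highest came without tumor replicate 9. Lists called were 21 in the main analysis, 19 after centring and scaling, 13 without tumor replicates 1 and 10, 16 without normal replicate 8 and tumor replicate 10, and 0 with an estimated correlation (lowest adjusted p = 0.082). Fry also called 21, but not exocrine pancreas (adjusted p = 0.0625), proteasome (0.114), matrix (0.127), mitosis (0.15), DNA replication (0.164) or ovary (0.267). It called instead the aryl hydrocarbon receptor battery (0.00182), oxidative stress (0.00946), coagulation (0.0229), translation (0.0296), complement (0.0437) and endothelium (0.0454). With the covariate 20 lists were called: nucleolus (0.169), hepatocyte transcription factors (0.175), mitosis (0.246) and ovary lost their call, and leukocytes (0.000461), interferon (0.00166) and oestrogen response gained one. Normal liver differed from the reference in 706 features at 2-fold. The distance difference was -0.127 as 1 minus the correlation, and -0.0818 to -0.0134 without each array.

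No sign was seen that the number in the titles pairs the samples: 2 of 10 pairs correlated above 0.1 (-0.152 to 0.122) and 1 of 10 arrays correlated best with its own number. A pairing hidden under differences between whole arrays is not excluded. With the number as a block, 1253 features were called, 668 higher and 585 lower, and 21 lists.

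Signs turned in results that were not called. With the covariate these were mbl2 (0.0342), clec14a (0.0567) and esr1 (-0.8323), and the lists of lipid synthesis (adjusted p = 0.404), hypoxia (0.273), skeletal muscle (0.896), Wnt (0.412), oestrogen response (0.0014, then called) and ovary (0.873, called before). Vtg3 turned in the rank-sum test (0.8641), without normal replicate 5 (0.3420) or 8 (0.1401), with -0.5592 as the lowest without any single array, without normal replicate 8 and tumor replicate 10 (0.3275) and without tumor replicates 1 and 10 (0.0548). Oestrogen response turned on centring (0.962), quantile normalization (0.804), scaling (0.731) and fry (0.999), and ribosomal proteins on quantile normalization (0.983), scaling (0.702) and without tumor replicates 1 and 10 (0.566). Without the latter, leukocytes (0.929) and skeletal muscle (0.781) turned, and leukocytes also without normal replicate 8 and tumor replicate 10 (0.906).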

Other observations

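Further lists that did not pass the list test held genes that moved both ways. Of 13 glycolysis genes 4 rose and 2 fell (camera adjusted p = 0.303), with lactate dehydrogenase ldha at 1.88 ± 0.43 and the phosphofructokinase pfkpa at 1.39 ± 0.28 beside the fall of gapdh. Of 15 hypoxia genes 4 rose and 3 fell (adjusted p = 0.468), with the vascular growth factor vegfab at -1.36 ± 0.25 and bnip3 at -1.12 ± 0.29. Of 26 genes of RAS, MAPK and MYC signalling 3 rose and 3 fell (adjusted p = 0.557). The transcription factor fosl2 rose by 1.52 ± 0.21, and the growth factors igf2a, igf2b and igf1 changed by -2.10 ± 0.35, -1.84 ± 0.36 and -1.99 ± 0.36. Of 23 genes named as markers of human liver cancer 7 rose and 4 fell (adjusted p = 0.251). Of 33 Wnt genes 2 rose and 3 fell (adjusted p = 0.731). Of 18 skeletal muscle genes 4 rose and 2 fell (adjusted p = 0.901), with a median of -0.21 and a mean of 0.10.

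Of 17 translation factors 4 rose and 1 fell (camera adjusted p = 0.0913), with eif5a2 at 0.96 ± 0.21. Of 5 genes of the aryl hydrocarbon receptor battery 2 fell, cyp1a and nqo1 (adjusted p = 0.0913), of 5 coagulation genes 1 fell, serpinc1 (-2.09 ± 0.39, adjusted p of the list 0.0947), and of 5 complement genes 1 fell, c8g (-1.52 ± 0.35, adjusted p of the list 0.133). Of 8 oxidative stress genes 2 rose and 3 fell (adjusted p = 0.177), with sod1 at -1.17 ± 0.26. In the endothelium list 1 of 13 genes fell, vegfab (adjusted p = 0.112), in oxidative phosphorylation 1 of 13, ndufb8 (-0.62 ± 0.18, lost without normal replicate 7 with adjusted p = 0.0519; adjusted p of the list 0.22), in lipid synthesis 1 of 10, fads2 (adjusted p = 0.731), and among oestrogen response genes 1 of 11, lpla (-1.37 ± 0.42, lost without any one of 12 arrays with adjusted p up to 0.0781; adjusted p of the list 0.981). Of 13 interferon and antigen presentation genes limma called 0 (3 at an unadjusted p under 0.05, 0 by the rank-sum test; adjusted p of the list 0.0913, and 0.00166 with the dim share as a covariate). Adjusted over the list alone, the counts of genes higher and lower were 5 and 2 in glycolysis, 6 and 3 in hypoxia, 5 and 4 in RAS, MAPK and MYC, 9 and 5 in the human liver cancer markers, 4 and 3 in Wnt, 4 and 2 in skeletal muscle, 5 and 2 in translation, 0 and 2 in the aryl hydrocarbon receptor battery, 1 and 3 in coagulation, 0 and 1 in complement, 2 and 3 in oxidative stress, 0 and 1 in endothelium, 0 and 1 in oxidative phosphorylation, 1 and 1 in lipid synthesis, 0 and 1 in oestrogen response, and 0 and 0 in interferon. The median and mean of lipid synthesis were 0.22 and -0.12, and those of RAS, MAPK and MYC 0.07 and -0.02.

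Probes named pax9, slc22a23, chst6 and tmem266, chosen after their values were seen, were near the reference on normal replicate 5, as vtg3 was. They stood there at 0.23, 0.48, 0.30 and 0.51, and over the 18 arrays other than normal replicates 5 and 8 their medians were -6.49, -6.36, -5.96 and -4.33, next to -7.07 for vtg3.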
